A study of Mus musculus with 24 samples.

How the data were processed

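The liver table held counts for 22355 genes by Entrez number in 24 libraries, 8 mice in each of 3 groups. Mice had received vehicle or IUB288, a glucagon receptor agonist known by its code name, for 4 d. Livers were taken 22 h after the last vehicle injection, and 4 h or 22 h after the last IUB288 injection. RNA had been prepared from frozen liver with the miRNeasy Mini Kit and libraries with the KAPA mRNA HyperPrep kit. According to the submitters' processing notes, reads were trimmed with cutadapt and aligned to GRCm38 with GSNAP. The versions of these tools, the counting tool, the gene annotation and the strand setting were not given in the sources used here. Reads were not processed again here.

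Each column was matched to its mouse by the name in the sample description. All 536520 values were whole and none was below 0. Totals ran from 14.0 to 44.1 M counts per library. Chi-square per degree of freedom ran from 21.0 to 358 over the 84 pairs of libraries within a group, so no 2 libraries were copies of each other or technical repeats. Genes were listed in the text order of their Entrez numbers, and the last number was 50932. Of 14657 RefSeq protein-coding genes that sort up to that number, 11720 were in the table, and of the 7243 that sort after it, none was. A 33.1% share of the 21900 RefSeq protein-coding genes, among them Fgf21, Foxo1, Crtc2 and Hamp, was therefore not analysed here. With those absent before that number, 11720 of the 21900 had a row. Symbols were those of the table, and 10794 of the genes tested (93.8%) had a RefSeq entry with the same Entrez number, from which coordinates were taken.

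An edgeR quasi-likelihood test had been fixed before the data were examined, but edgeR was not run here. An automated check of units did not accept the quoted, space-separated layout of the table as counts, and tools that need counts were therefore left out. The limma-voom test, fixed earlier as an alternative, took its place with the same filter, scaling, libraries and model. DESeq2, another alternative fixed earlier, was not run either.

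Genes were kept when their expression passed a filter on the 3 groups with a minimum count of 10 and a minimum total of 15, which left 11508 genes with 99.92% of all counts. Counts were scaled by TMM, written out in R with trims of 30% of log ratios and 5% of mean log expression on each side. Weights came from voom with an offset of 0.5, and 1 linear model held the means of the 3 groups, with 21 residual and 4.08 prior degrees of freedom. Empirical Bayes tests of limma were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The 22 h against 4 h comparison was the test of the difference between the other 2. CPM values are given as mean ± SD over 8 mice, and log2 fold changes with their standard error from the model where one is shown. Mice on the same side means treated (or later) livers whose log2 CPM lay on the side of the change from the mean of the other group.

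The 48 gene lists, 10 of them markers of other cell types, were fixed together with the tests and share genes such as Tat, Got1, Pck1 and Irs2. Lists were tested on voom values with camera, 2-sided, with a preset correlation of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were counted only over those in the table that passed the expression filter. Other members of a list as drawn up, such as Fgf21, Foxo1, Crtc2 and Hamp, were not tested, so counts do not cover whole pathways. Members were also counted as higher or lower after adjustment over the list alone. Named genes were 8 fixed ones, the 8 largest rises and 8 largest falls per comparison with at least 5 CPM in 1 group and all 8 mice on the same side, and the list members with the smallest p and at least 1 CPM. Gene models with no established name were left out. Further genes are said to have been chosen after their values were seen.

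Both comparisons with vehicle used the same 8 vehicle livers, whose chance values push both changes the same way. The overlap, the correlation and the share of the 4 h change left at 22 h were therefore also taken with 4 vehicle livers for one comparison and the other 4 for the other. The share left is the slope through the origin of the 22 h change on the 4 h change over genes called at 4 h, the mean of replicates 1 to 4 against 5 to 8 and the reverse, with the range over 20 seeded splits. Unchanged groups, drawn around the observed vehicle means, were simulated 20 times against the same vehicle livers. The gene test, camera and the share left were also run on simulated counts with known changes. At 4 h the gene test found 47.8%, 73.1% and 89.4% of changes of 1.5-fold, 2-fold and 4-fold, with 5 false among 145 calls. A share left of 50% was found as 45.3%. None of 48 simulated lists of unchanged genes was called, but their genes were drawn independently of each other.

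Counts of genes were recomputed with median-of-ratios and upper-quartile scaling, no filter, a stricter filter of 1 CPM in 8 libraries, the 16 libraries of a comparison alone, the replicate number as a block, the run of mouse numbers (1 to 12 or 13 to 24) as a covariate, each run alone, a test against a fold change of 1.5, and each library left out. Named genes and lists were recomputed in the same ways, except against a fold change of 1.5 and, for lists, within each run. After the data were seen, limma-trend (not for lists), library quality weights and fits without vehicle replicates 2 and 7 and 4 h replicate 8, or without 22 h replicates 6 and 7, were added. The 16 libraries of each comparison were also fitted in 100 splits into 8 and 8, the real one included. Dixon's test was run in each group of 8 on named genes, library totals and marker lists, and results of some of these genes, 1 outlying value among them, are not reported here. Copies of genes were searched with blastn 2.17.0 at 95% identity over 200 bases. R was 4.3.3 and limma 3.58.1, and seeds were fixed.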

Results

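Liver RNA was sequenced from 24 diet-induced obese mice that had received vehicle or the glucagon receptor agonist IUB288 for 4 d, 8 mice per group. Vehicle livers were taken 22 h after the last injection, and IUB288 livers 4 h or 22 h after it. Library totals were 31.8 ± 9.49 M counts for vehicle (SD, n = 8), 31.3 ± 3.66 M at 4 h and 31.3 ± 2.85 M at 22 h. Between 14093 and 17371 genes had a count in a library. Alb, the gene of serum albumin, had the most counts in all 24 libraries, and the 10 highest genes took 24.1% to 26.3% of counts in vehicle, 20.0% to 21.6% at 4 h and 19.6% to 21.7% at 22 h. Vehicle replicate 1 also held Ucp1, the uncoupling protein of brown fat, at 1390 CPM, against at most 0.576 CPM in any other library. The table used here held genes up to an Entrez number in text order. The 33.1% of RefSeq protein-coding genes that sort after it were not analysed here. Of all 21900 such genes 11720 were in the table, and members of gene lists are counted only over those tested.

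At 4 h, genes of glucose production and of the cAMP response were higher than in vehicle livers. Pck1, which makes phosphoenolpyruvate for gluconeogenesis, rose from 1317 ± 359.3 to 6819 ± 1206 CPM (SD, n = 8; log2 fold change 2.39 ± 0.20, limma-voom adjusted p = 3.47e-10). G6pc, which releases free glucose, rose from 280.3 ± 102.3 to 1378 ± 261.6 CPM (2.40 ± 0.31, limma-voom adjusted p = 6.41e-07). Ppargc1a, a coactivator that drives both, rose from 27.26 ± 4.47 to 137.1 ± 43.51 CPM (2.28 ± 0.14, limma-voom adjusted p = 1.47e-12). All 8 treated livers lay above the vehicle mean for each. On GRCm38, Pck1 (Entrez 18534) lies at 2:173153073-173159274, G6pc (14377) at 11:101367716-101377903 and Ppargc1a (19017) at 5:51454249-52115853. In the gluconeogenesis list 14 of 19 members were higher, 1 lower and 4 not called, against 14, 2 and 3 adjusted over the list alone (camera adjusted p = 4.79e-06, and adjusted p = 0.256 with an estimated correlation). Fbp1, which splits fructose bisphosphate, and Got1, the cytosolic aspartate aminotransferase, were among its clearest rises, by 1.08 and 3.39 log2 units (limma-voom adjusted p = 2.49e-11 and 3.21e-12, 8 of 8 livers).

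The cAMP-response factor CREB has early target genes that code for transcription factors and for brakes on its own signal. Crem (log2 fold change 2.46), Sik1 (2.64), which holds back CREB coactivators, and the orphan receptor gene Nr4a3 (4.63) rose in all 8 livers (limma-voom adjusted p = 6.07e-16, 1.04e-13 and 2.29e-13). In this list 14 of 23 members were higher, 3 lower and 6 not called, the same as adjusted over the list alone (camera adjusted p = 5.97e-07, and adjusted p = 0.256 with an estimated correlation). Glucocorticoid, FOXO and fasting response genes also rose, led by Tat, the first enzyme of tyrosine breakdown, from 512.2 ± 161.6 to 5387 ± 1092 CPM (SD, n = 8; 3.42, limma-voom adjusted p = 2.31e-13, 8 of 8). Irs2, which carries the insulin signal, rose by 2.35 (limma-voom adjusted p = 3.47e-12, 8 of 8). Of these 18 members 12 were higher, 3 lower and 3 not called, against 13, 4 and 1 adjusted over the list alone (camera adjusted p = 0.00304, and adjusted p = 0.411 with an estimated correlation). Per1, a clock gene with a cAMP response element, at 11:69095108-69109965 (GRCm38, Entrez 18626), rose from 26.06 ± 5.706 to 50.47 ± 11.31 CPM (0.97, limma-voom adjusted p = 0.000898, 8 of 8).

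Amino acid breakdown and nitrogen disposal rose with glucose production. Tat and Got1 were again the members with the smallest p of the amino acid catabolism list, where 25 of 37 were higher, 2 lower and 10 not called, against 26, 2 and 9 adjusted over the list alone (camera adjusted p = 1.09e-09, and adjusted p = 0.411 with an estimated correlation). In the urea cycle, Slc25a15, the mitochondrial ornithine carrier, rose by 2.07 log2 units, the liver glutaminase gene Gls2 by 1.88 and Ass1, which makes argininosuccinate, by 1.60 (limma-voom adjusted p = 7.02e-13, 2.78e-11 and 1.37e-10, 8 of 8 livers each). That list had 8 of 12 members higher, 1 lower and 3 not called, against 8, 2 and 2 adjusted over the list alone (camera adjusted p = 0.000187, and adjusted p = 0.411 with an estimated correlation). Among amino acid transporters, Slc7a2, which carries cationic amino acids, rose by 2.53 and Slc3a2, the shared heavy chain, by 1.71 (limma-voom adjusted p = 8.03e-12 and 6.84e-12, 8 of 8). Of 10 transporters 5 were higher, 1 lower and 4 not called, also adjusted over the list alone (camera adjusted p = 0.042, and adjusted p = 0.256 with an estimated correlation). That call was lost without 22 h replicate 7 (adjusted p = 0.052), with the 16 libraries of the comparison alone (0.0626) and with the stricter filter (0.0691). Nnmt, which spends methyl groups on nicotinamide, and the transsulfuration genes Cth and Cbs rose by 3.59, 2.47 and 1.28 (limma-voom adjusted p = 4.88e-14, 4.37e-10 and 4.69e-10, 8 of 8). The methionine and one-carbon list had 9 of 20 higher, 1 lower and 10 not called, against 10, 1 and 9 adjusted over the list alone (camera adjusted p = 0.00332, and adjusted p = 0.541 with an estimated correlation).

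Genes of the ATF4, heat shock, ribosome biogenesis and mitochondrial biogenesis lists were higher as well. Atf5, a factor induced through the integrated stress response, rose by 1.23 log2 units and the stress hormone gene Gdf15 by 1.98 (limma-voom adjusted p = 1.42e-09 and 1.56e-08, 8 of 8 livers). In the ATF4 list 10 of 18 members were higher, none lower and 8 not called, against 11, 0 and 7 adjusted over the list alone (camera adjusted p = 0.000305, and adjusted p = 0.411 with an estimated correlation). Hspd1, the mitochondrial chaperonin, and Hspa8, the constitutive Hsc70, rose by 0.47 and 0.63 (limma-voom adjusted p = 5.44e-07 and 1.61e-05, 8 of 8). Cytosolic heat shock had 8 of 11 higher and 3 not called, also adjusted over the list alone (camera adjusted p = 0.00658, and adjusted p = 0.541 with an estimated correlation). Gnl3 and Ncl, which code for the nucleolar proteins nucleostemin and nucleolin, rose by 0.91 and 0.43 (limma-voom adjusted p = 2.42e-12 and 5.66e-07, 8 of 8). Ribosome biogenesis had 11 of 13 higher, 1 lower and 1 not called, also adjusted over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.256 with an estimated correlation). Fh1, the fumarase of the tricarboxylic acid cycle, rose by 1.76 (limma-voom adjusted p = 8.96e-12, 8 of 8). Together with Ppargc1a it led the list of mitochondrial biogenesis and this cycle, with 9 of 21 higher, 2 lower and 10 not called, also adjusted over the list alone (camera adjusted p = 0.0273, and adjusted p = 0.593 with an estimated correlation).

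Cholesterol and fatty acid synthesis were lower at 4 h. Hmgcs1, which feeds the mevalonate pathway, fell from 859.1 ± 216 to 174.7 ± 55.18 CPM (SD, n = 8; log2 fold change -2.32, limma-voom adjusted p = 2.25e-10) and the acetyl-CoA acetyltransferase gene Acat2 changed by -1.08 (limma-voom adjusted p = 1.68e-09), in 8 of 8 livers each. Of 21 cholesterol genes none was higher, 18 were lower and 3 not called, also adjusted over the list alone (camera adjusted p = 3.42e-09, and adjusted p = 0.411 with an estimated correlation). Gpam, the first step of glycerolipid synthesis, changed by -1.71, the lipogenic regulator gene Thrsp by -2.02 and the desaturase gene Scd1 by -2.05, from 33250 ± 11330 to 8946 ± 4432 CPM (SD, n = 8; limma-voom adjusted p = 9.35e-11, 3.39e-06 and 0.000121, 8 of 8). Srebf1, the lipogenic transcription factor at 11:60199084-60224186 (GRCm38, Entrez 20787), fell from 180.1 ± 49.46 to 114.1 ± 29.45 CPM (-0.65, limma-voom adjusted p = 0.00793, 8 of 8). The lipogenesis list had 1 of 13 higher, 8 lower and 4 not called, against 1, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00946, and adjusted p = 0.593 with an estimated correlation).

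Genes of the periportal zone, where glucose and urea are made, were higher, and pericentral genes were lower. Gls2, Ass1 and Pck1 led the periportal markers, 13 of 18 of which were higher, 4 lower and 1 not called, also adjusted over the list alone (camera adjusted p = 0.000321, and adjusted p = 0.541 with an estimated correlation). Cyp27a1, a sterol hydroxylase of bile acid synthesis, changed by -0.74 log2 units and the calcium-binding protein gene Rgn by -1.65 (limma-voom adjusted p = 5.62e-10 and 1.42e-09, 8 of 8 livers). Pericentral markers were higher for 3 of 19, lower for 9 and not called for 7, also adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.593 with an estimated correlation). As drawn up, the periportal list shares Gls2, Ass1, Asl, Arg1 and Cps1 with the urea cycle list and Pck1, Sds and Sdsl with gluconeogenesis. It also shares Hal, Uroc1 and Ftcd with amino acid catabolism and was no independent result. Whether zones or only these pathways changed was not tested.

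Markers of stellate, endothelial and erythroid cells were lower at 4 h. Tagln, an actin-binding protein of contractile cells, and Postn, a matrix protein, changed by -0.85 and -0.94 log2 units (limma-voom adjusted p = 6.08e-05 and 0.0012, 8 of 8 livers). Stellate cell and fibroblast markers were lower for 9 of 17, higher for none and not called for 8, against 10, 0 and 7 adjusted over the list alone (camera adjusted p = 0.00658, and adjusted p = 0.593 with an estimated correlation). The vessel genes Egfl7 and Flt4 each changed by -0.63 (limma-voom adjusted p = 0.000473 and 0.00344, 8 of 8). Endothelial markers were lower for 4 of 17 and not called for 13, against 2 and 15 adjusted over the list alone (camera adjusted p = 0.042, and adjusted p = 0.637 with an estimated correlation). This call was lost without vehicle replicate 3, 4, 5 or 8 or 4 h replicate 5 or 6 (adjusted p = 0.0547 to 0.0837). Globin genes of red cells, Hba-a2, Hba-a1 and Hbb-bs, changed by -1.28, -1.17 and -1.17 (limma-voom adjusted p = 1.91e-06, 1.88e-05 and 5.47e-05, 8 of 8), although reads of such near-identical genes are uncertain. Erythroid markers were higher for 1 of 7, lower for 5 and not called for 1, also adjusted over the list alone (camera adjusted p = 0.0266, and adjusted p = 0.541 with an estimated correlation).

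Immune genes were lower too, in part because of a single vehicle library. Gbp7, an interferon-induced GTPase, and Ddx58, the viral RNA sensor RIG-I, changed by -0.88 and -0.39 log2 units (limma-voom adjusted p = 0.000191 and 0.00119, 8 of 8 livers). Interferon genes were lower for 8 of 23, higher for none and not called for 15, also adjusted over the list alone (camera adjusted p = 0.0232, and adjusted p = 0.637 with an estimated correlation). That call was lost without vehicle replicate 1 (adjusted p = 0.0934). The heavy chain gene Ighm of B cells changed by -1.27 and the light chain gene Igkc by -1.0 (limma-voom adjusted p = 0.00358 and 0.0493, 8 of 8). Igkc lost its call without vehicle replicate 1 (log2 fold change -0.57) and without any of 14 other single libraries. T, NK and B cell markers were lower for 6 of 18 and not called for 12, against 2 and 16 adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.593 with an estimated correlation). This call was lost without vehicle replicate 1 (adjusted p = 0.0643), with quality weights (0.078) and for members of at least 1 CPM (0.176).

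The largest rises at 4 h were a mixed group of membrane, hormone and signalling genes, all in 8 of 8 livers. Tmem266, which codes for a voltage-sensing membrane protein, rose 32.4-fold, the little-studied Fam222a 30.6-fold and Nr4a3 24.8-fold, from 1.74 ± 1.417 to 39.25 ± 5.794 CPM (SD, n = 8; limma-voom adjusted p = 2.38e-08, 3.31e-09 and 2.29e-13). Lrp2, the endocytic receptor megalin, rose 21.5-fold, the aldo-keto reductase gene Akr1b7 18.9-fold and Fst, whose secreted product follistatin binds activins, 16.4-fold (limma-voom adjusted p = 0.000139, 0.000108 and 1.54e-12). Gucy2c, a guanylate cyclase receptor, rose 16-fold and the phosphatase-like Tpte 14.4-fold (limma-voom adjusted p = 1.85e-06 and 1.21e-09). The largest fall was that of Rgs16, which turns off signals of G protein-coupled receptors, 247-fold from 243.5 ± 69.71 to 1.159 ± 0.8499 CPM (SD, n = 8; limma-voom adjusted p = 6.53e-11). Depp1, a FOXO target, fell 40.2-fold, Arrdc3, an arrestin family gene, 24.8-fold and Orm3, an acute phase gene, 14-fold (limma-voom adjusted p = 3.6e-09, 1.11e-15 and 3.71e-10). The carboxylesterase gene Ces1g fell 10.0-fold, with a copy-rich family that leaves its reads uncertain, and Chrna4, a nicotinic receptor subunit, 9.08-fold (limma-voom adjusted p = 1.47e-12 and 3.54e-08). Pnpla3, a lipid droplet lipase, fell 16.1-fold and Aqp7, a glycerol channel, 9.45-fold (limma-voom adjusted p = 0.00535 and 0.00466). Without vehicle replicate 1 these 2 fell 10.2-fold and 6.15-fold.

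At 4 h the receptor gene of the drug and 1 of 2 bile acid genes named in advance were lower. Gcgr, the glucagon receptor gene at 11:120529185-120538989 (GRCm38, Entrez 14527), fell from 118.6 ± 14.8 to 89.75 ± 6.051 CPM (SD, n = 8; log2 fold change -0.39 ± 0.09, limma-voom adjusted p = 0.00147, 8 of 8 livers). Cyp8b1, the sterol hydroxylase needed for cholic acid, at 9:121914356-121916305 (Entrez 13124), fell from 234.6 ± 78.81 to 137.6 ± 70.09 CPM (-0.82, limma-voom adjusted p = 0.0057, 7 of 8). Cyp7a1, the first step of bile acid synthesis at 4:6265612-6275632 (Entrez 13122), was not called at 282.5 ± 132.6 and 234.2 ± 93.96 CPM (-0.27, limma-voom adjusted p = 0.531, 5 of 8). Bile acid synthesis had 1 of 13 genes higher, 4 lower and 8 not called (camera adjusted p = 0.188), and bile acid transport and FXR targets had 2, 3 and 8 (camera adjusted p = 0.95).

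Lipid handling outside synthesis was not called as a group at 4 h. Fatty acid oxidation and PPARA targets had 6 of 32 members higher, 14 lower and 12 not called (camera adjusted p = 0.0567), ketogenesis 0, 3 and 3 of 6 (camera adjusted p = 0.125) and lipid droplets and triglyceride storage 1, 8 and 2 of 11 (camera adjusted p = 0.0505). Fatty acid oxidation was called lower without any one of vehicle replicates 2 and 3, 4 h replicates 3, 4 and 8 and 22 h replicates 6 and 8 (adjusted p = 0.0341 to 0.0485). Lipid droplet genes were called lower without any one of vehicle replicates 2 to 6, 4 h replicates 3, 4, 7 and 8 and 22 h replicates 6 and 8 (adjusted p = 0.0355 to 0.0497). Lipoprotein and sterol transport had 3, 6 and 12 of 21 (camera adjusted p = 0.23) and glycolysis and glycogen 4, 6 and 6 of 16 (camera adjusted p = 0.23). Mitochondrial oxidative phosphorylation had 3 of 18 higher and 15 not called (camera adjusted p = 0.388) but was called higher without vehicle replicate 1 (adjusted p = 0.00329). Autophagy and lysosome had 9 of 20 higher, 4 lower and 7 not called (camera adjusted p = 0.115).

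Other groups of genes were mixed at 4 h. Xenobiotic metabolism had 4 of 20 members higher, 9 lower and 7 not called (camera adjusted p = 0.0884; without vehicle replicate 2 adjusted p = 0.0497), NRF2 targets 8, 2 and 9 of 19 (0.159) and endoplasmic reticulum chaperones 7, 1 and 4 of 12 (0.0908; without 22 h replicate 6 adjusted p = 0.0456), by camera. The clock list had 7, 6 and 5 of 18 (camera adjusted p = 0.374), with Hlf at -0.86 and Nfil3 at 1.84 log2 units (limma-voom adjusted p = 2.42e-10 and 1.1e-09, 8 of 8 livers). Camera gave adjusted p = 0.157 for hepatokines (8, 4 and 8 of 20), 0.283 for acute phase genes (5, 11 and 10 of 26), 0.495 for the cell cycle (2, 3 and 28 of 33), 0.586 for metals (6, 4 and 5 of 15). Camera adjusted p was 0.472 for actin and SRF targets (3, 6 and 8 of 17), 0.496 for vitamin A and nuclear receptor genes (4, 6 and 12 of 22), 0.629 for female-biased genes (4, 5 and 5 of 14), 0.629 for glucagon-related receptors (5, 5 and 7 of 17) and 0.95 for male-biased genes (4, 1 and 14 of 19). In the last 2 of these the median change was below 0 (-0.12 and -0.24) while the mean (0.17 and 0.01) and the direction of the test were up. Among markers, Kupffer cells had 0, 5 and 10 of 15 (camera adjusted p = 0.107), cholangiocytes 1, 5 and 6 of 12 (0.135; without vehicle replicate 1 adjusted p = 0.0469). Neutrophils and monocytes had 0, 1 and 9 of 10 (camera adjusted p = 0.283), adipocytes 1, 4 and 2 of 7 (0.279), muscle 0, 1 and 2 of 3 (0.518) and pancreas 0, 0 and 1 of 1 (0.55). Adjusted over the list alone, the counts of the lists not called at 4 h moved by at most 2 members.

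In total 2501 genes rose and 2590 fell at 4 h, 5091 or 44.2% of 11508 tested, 492 and 749 of them by at least 2-fold (limma-voom adjusted p < 0.05). Upper-quartile scaling moved the share of rises from 49.1% to 39.3%. Within mice 1 to 12, which include vehicle replicate 1, there were 2144 such genes. Within mice 13 to 24 there were 3927, with 4 against 4 livers in each run. Of 48 lists camera called 12 higher and 8 lower, and with an estimated correlation none, while fry called 35. Other splits of the 16 libraries gave a median of 11 lists called by camera. Vehicle livers were taken only at 22 h, so this comparison also set 4 h against 22 h after an injection.

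**Figure D1:**
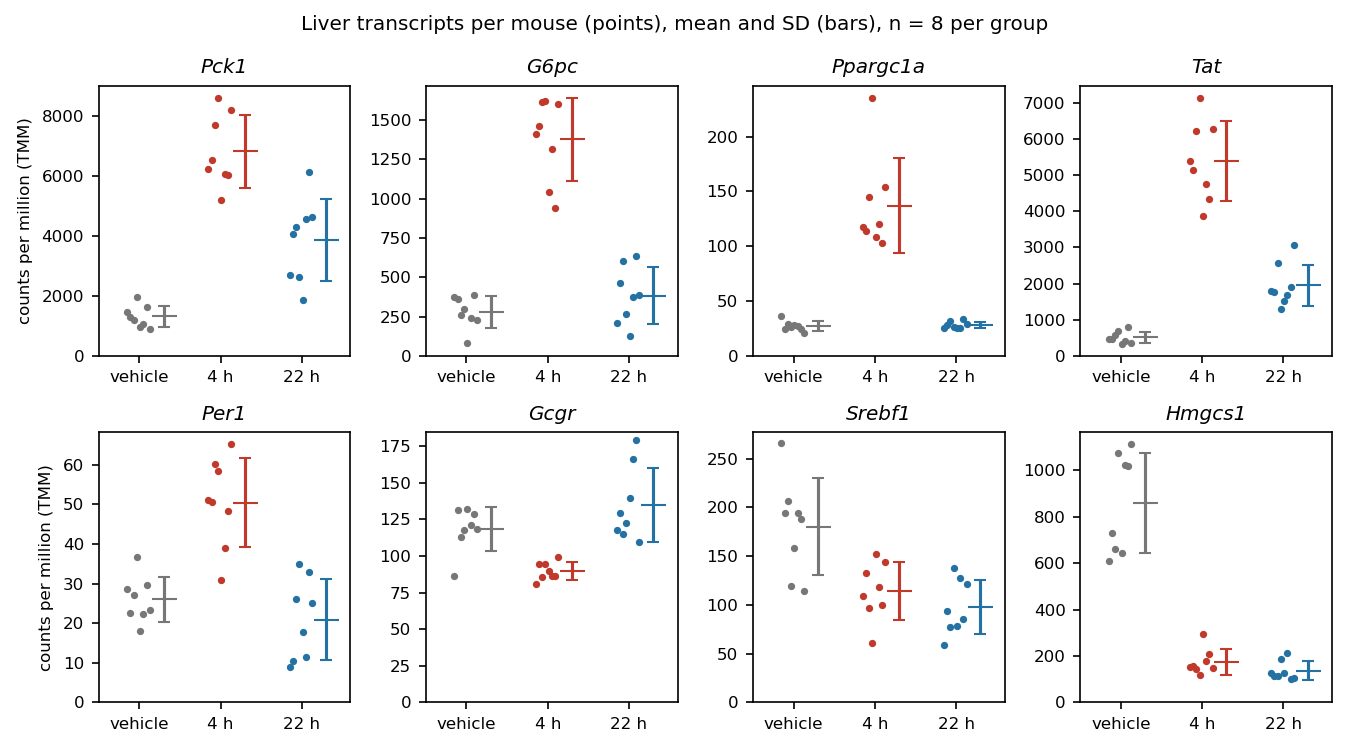
CPM of Pck1, G6pc, Ppargc1a, Tat, Per1, Gcgr, Srebf1 and Hmgcs1 in each of the 24 livers, with the mean and SD of each group of 8.

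After 22 h, genes of glucose production and amino acid breakdown were still higher than in vehicle livers, although G6pc and Ppargc1a were not. Pck1 was at 3860 ± 1378 CPM against 1317 ± 359.3 (SD, n = 8; 2.84-fold, limma-voom adjusted p = 1.5e-06, 8 of 8 livers). G6pc (0.41, limma-voom adjusted p = 0.297, 6 of 8), Ppargc1a (0.04, limma-voom adjusted p = 0.856, 4 of 8) and Per1 (-0.46, limma-voom adjusted p = 0.146, 5 of 8) were not called. Fbp1, Tat and Got1 stayed higher by 1.19, 1.92 and 2.20 (limma-voom adjusted p = 1.82e-11, 9.85e-09 and 1.47e-08, 8 of 8). Pcx, the pyruvate carboxylase that starts gluconeogenesis, was lower at -0.66 (limma-voom adjusted p = 1.51e-09, 8 of 8). Gluconeogenesis had 10 of 19 members higher, 1 lower and 8 not called, against 11, 1 and 7 adjusted over the list alone (camera adjusted p = 2e-05, and adjusted p = 0.192 with an estimated correlation). The CREB list was not called, with 8 of 23 higher, 4 lower and 11 not called, against 11, 4 and 8 adjusted over the list alone (camera adjusted p = 0.145; without vehicle replicate 1 adjusted p = 0.0265). Nor was the glucocorticoid and fasting list, with 7, 3 and 8 of 18 (camera adjusted p = 0.425), whose median change was -0.01 and mean 0.23.

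Nitrogen handling kept its rise. The transsulfuration genes Cbs and Cth were higher by 1.72 and 2.36 log2 units, and Hgd, which breaks down homogentisate from tyrosine, by 1.36 (limma-voom adjusted p = 1.54e-11, 3.29e-09 and 1.02e-10, 8 of 8 livers). Amino acid catabolism had 26 of 37 genes higher, none lower and 11 not called, against 27, 0 and 10 adjusted over the list alone (camera adjusted p = 9.42e-17, and adjusted p = 0.159 with an estimated correlation). Gls2 was higher by 2.23 and Ass1 by 1.80, from 772.3 ± 138.1 to 2687 ± 465.5 CPM (SD, n = 8; limma-voom adjusted p = 1.01e-11 and 7.22e-11, 8 of 8). The urea cycle had 8 of 12 higher, 1 lower and 3 not called, against 9, 1 and 2 adjusted over the list alone (camera adjusted p = 1.86e-05, and adjusted p = 0.213 with an estimated correlation). Slc7a2 was higher by 1.81 and Slc6a12, a betaine transporter, by 0.68 (limma-voom adjusted p = 7.93e-09 and 3.97e-05, 8 of 8). Amino acid transporters had 4 of 10 higher, 1 lower and 5 not called, against 5, 1 and 4 adjusted over the list alone (camera adjusted p = 0.0377, and adjusted p = 0.159 with an estimated correlation). They lost the call without vehicle replicate 2 (adjusted p = 0.0534), without vehicle replicates 2 and 7 and 4 h replicate 8 (0.0565) and with the stricter filter (0.0689). Nnmt was at 348.3 ± 81.78 against 44.67 ± 11.37 CPM (SD, n = 8; 2.97, limma-voom adjusted p = 7.25e-12, 8 of 8). Methionine and one-carbon metabolism had 8 of 20 higher, 2 lower and 10 not called, against 11, 2 and 7 adjusted over the list alone (camera adjusted p = 0.000911, and adjusted p = 0.331 with an estimated correlation). Periportal markers, again Gls2, Ass1 and Pck1, had 13 of 18 higher, 4 lower and 1 not called, also adjusted over the list alone (camera adjusted p = 1.83e-06, and adjusted p = 0.213 with an estimated correlation). With the genes it shares with the lists above, the periportal list was again no independent result.

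Genes of the ATF4, heat shock and ribosome biogenesis lists also remained higher at 22 h. Atf5 was up by 1.99 log2 units, more than at 4 h, and Gdf15 by 1.45 (limma-voom adjusted p = 4.12e-12 and 9.48e-06, 8 of 8 livers). ATF4 genes were higher for 8 of 18, lower for 1 and not called for 9, against 9, 1 and 8 adjusted over the list alone (camera adjusted p = 0.000479, and adjusted p = 0.323 with an estimated correlation). Hspd1 and the Hsp90 gene Hsp90ab1 were up by 0.48 and 0.51 (limma-voom adjusted p = 1.24e-06 and 2.79e-06, 8 of 8). Heat shock had 7 of 11 higher and 4 not called, also adjusted over the list alone (camera adjusted p = 0.000262, and adjusted p = 0.306 with an estimated correlation). Ahsg, which codes for the secreted glycoprotein fetuin-A, was up by 1.11 and Fst by 2.12 (limma-voom adjusted p = 5.13e-08 and 7.93e-07, 8 of 8). Hepatokines, not called as a list at 4 h, had 9 of 20 higher, 5 lower and 6 not called, against 10, 6 and 4 adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.213 with an estimated correlation). Gnl3 and Nop16, another nucleolar gene, were up by 0.51 and 0.59 (limma-voom adjusted p = 2.26e-07 and 5.14e-05, 8 of 8). The ribosome biogenesis list had 8 of 13 higher and 5 not called, against 10 and 3 adjusted over the list alone (camera adjusted p = 0.000154, and adjusted p = 0.159 with an estimated correlation).

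Lipid synthesis was still lower at 22 h. Hmgcs1 was at 136.5 ± 41.34 against 859.1 ± 216 CPM (SD, n = 8; log2 fold change -2.67, limma-voom adjusted p = 7.22e-11) and Acat2 changed by -1.28 (limma-voom adjusted p = 3.97e-10), 8 of 8 livers each. Cholesterol genes were lower for 20 of 21 and not called for 1, also adjusted over the list alone (camera adjusted p = 1.15e-18, and adjusted p = 0.159 with an estimated correlation). Scd1 was at 3244 ± 1559 against 33250 ± 11330 CPM (SD, n = 8; -3.45), Thrsp changed by -3.16 and Acacb, which makes the malonyl-CoA that restrains fat oxidation, by -1.96 (limma-voom adjusted p = 1.65e-07, 1.47e-08 and 5.13e-08, 8 of 8). Srebf1 changed by -0.89 to 97.58 ± 27.95 CPM (SD, n = 8; limma-voom adjusted p = 0.000965, 8 of 8). Lipogenic genes were lower for 12 of 13 and not called for 1, against 13 and 0 adjusted over the list alone (camera adjusted p = 3.78e-08, and adjusted p = 0.159 with an estimated correlation). Cidec and Fitm2, which build lipid droplets, changed by -1.98 and -0.81 (limma-voom adjusted p = 2.49e-06 and 5.31e-06, 8 of 8). The lipid droplet list had 8 of 11 lower and 3 not called, against 9 and 2 adjusted over the list alone (camera adjusted p = 0.000411, and adjusted p = 0.159 with an estimated correlation). The monocarboxylate carrier gene Slc16a7 changed by -0.50 (limma-voom adjusted p = 8.33e-05, 8 of 8). Ketogenesis had 3 of 6 lower and 3 not called, also adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.159 with an estimated correlation).

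Markers of several other cell types of the liver were lower at 22 h. Tagln and Postn changed by -1.38 and -1.80 log2 units (limma-voom adjusted p = 6.26e-07 and 5.34e-06, 8 of 8 livers). Stellate and fibroblast markers were lower for 16 of 17 and not called for 1, also adjusted over the list alone (camera adjusted p = 2.09e-07, and adjusted p = 0.213 with an estimated correlation). All 17 endothelial markers were lower, also adjusted over the list alone (camera adjusted p = 2.68e-07, and adjusted p = 0.278 with an estimated correlation). Among them Vwf, the clotting factor carrier, changed by -1.04 and the junction gene Cdh5 by -1.19 (limma-voom adjusted p = 5.32e-05 and 0.000292, 8 of 8). C1qb, a complement subunit, and Folr2, a folate receptor of macrophages, changed by -1.02 and -1.40 (limma-voom adjusted p = 0.00016 and 0.00075, 8 of 8). Kupffer cell markers were lower for 10 of 15 and not called for 5, against 12 and 3 adjusted over the list alone (camera adjusted p = 0.000678, and adjusted p = 0.467 with an estimated correlation). Cd79a, a subunit of the B cell receptor, and Ighm changed by -1.47 and -1.07 (limma-voom adjusted p = 0.00431 and 0.0116, 8 and 7 of 8). Ighm lost its call without 22 h replicates 6 and 7 together (-0.86). Of 18 T, NK and B cell markers 6 were lower and 12 not called, also adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.545 with an estimated correlation). This call was lost without 22 h replicates 6 and 7 (adjusted p = 0.0847), with library quality weights (0.182) and for members of at least 1 CPM (0.217). Replicates 6 and 7 stood apart from the other 22 h livers on the second principal component (-57.14 and -61.46, against -30.9 to -13.15). They held the 2 lowest 22 h averages of stellate (2.883 and 2.77 log2 CPM), endothelial (4.096 and 4.086) and T, NK and B cell markers (-1.287 and -1.984). The globin genes Hba-a2, Hbb-bs and Hba-a1, uncertain as near-identical genes, changed by -2.35, -2.11 and -2.20 (limma-voom adjusted p = 3.48e-09, 6.11e-08 and 6.11e-08, 8 of 8). Erythroid markers had 1 of 7 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.000154, and adjusted p = 0.213 with an estimated correlation). Cholangiocyte markers, with 1 of 12 higher, 4 lower and 7 not called, and neutrophil and monocyte markers, with 0, 2 and 8 of 10, were not called (camera adjusted p = 0.315 and 0.259). A change in RNA per cell and a change in cell number cannot be told apart here.

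Interferon genes were lower in the same livers, and few cell cycle genes were. Oasl2, an antiviral synthetase-like gene, and the GTPase gene Gbp7 changed by -1.30 and -0.76 log2 units (limma-voom adjusted p = 0.00101 and 0.00133, 8 of 8 livers). Interferon genes were lower for 12 of 23 and not called for 11, against 13 and 10 adjusted over the list alone (camera adjusted p = 0.000339, and adjusted p = 0.539 with an estimated correlation). Of the replication helicase genes, Mcm4 changed by -0.67 and Mcm7 by 0.41 (limma-voom adjusted p = 0.00481 and 0.00109, 7 and 8 of 8). The cell cycle list had 1 of 33 higher, 7 lower and 25 not called, against 1, 3 and 29 adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.731 with an estimated correlation). This call was lost without any one of vehicle replicates 2, 7 and 8 and 22 h replicates 5 and 7 (adjusted p = 0.0585 to 0.179), and without 22 h replicates 6 and 7 together (0.154). It was also lost without vehicle replicates 2 and 7 and 4 h replicate 8 (0.115), by fry (0.153), with quality weights (0.117), with the stricter filter (0.0536) and with the block (0.0577).

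The largest rises against vehicle at 22 h, in 8 of 8 livers each, were of enzymes and membrane proteins. Akr1b7 was 17.4-fold higher, Lrp2 13.3-fold, Gucy2c 10.9-fold and Nptx1, a neuronal pentraxin, 10.3-fold (limma-voom adjusted p = 0.000301, 0.00161, 4.58e-05 and 1.12e-05). The steroid hydroxylase gene Cyp2a4 was 9.31-fold higher, uncertain because Cyp2a5 is nearly identical, and Nnmt 7.82-fold (limma-voom adjusted p = 6.26e-07 and 7.25e-12). Acmsd, which diverts tryptophan from NAD synthesis, was 7.41-fold and Cyp17a1, which makes androgen precursors, 7.27-fold higher (limma-voom adjusted p = 7.05e-09 and 2.5e-08). Chrna4 fell 49.6-fold to 0.2695 ± 0.1633 CPM (SD, n = 8), the T cell development gene Themis 13-fold and Cfd, the complement factor adipsin, 12.3-fold (limma-voom adjusted p = 9.12e-08, 2.26e-09 and 0.000999). Themis was at 55.4 to 96.4 CPM in vehicle livers, where T, NK and B cell markers averaged at most 1.275 log2 CPM. Its fall was therefore not read as a loss of T cells. Orm3 fell 11.0-fold, Scd1 10.9-fold and Pnpla3 15.2-fold, or 9.65-fold without vehicle replicate 1 (limma-voom adjusted p = 1.67e-09, 1.65e-07 and 0.00644). Ugt1a5, a glucuronosyltransferase that shares exons with its neighbours, fell 19.2-fold and Ces1g 12.1-fold, both uncertain for that reason (limma-voom adjusted p = 1.82e-11 and 4.12e-12).

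Of the genes named in advance, Gcgr (0.18, limma-voom adjusted p = 0.145, 6 of 8 livers), Cyp7a1 (0.27, limma-voom adjusted p = 0.554, 5 of 8) and Cyp8b1 (-0.12, limma-voom adjusted p = 0.731, 6 of 8) were not called at 22 h. Pericentral markers had 2 of 19 higher, 10 lower and 7 not called (camera adjusted p = 0.0515). Leaving out any one of 9 libraries brought a call (adjusted p = 0.0175 to 0.0489, vehicle replicates 1, 2, 3 and 6, 4 h replicate 6 and 22 h replicates 2, 4, 6 and 7). Mitochondrial oxidative phosphorylation (camera adjusted p = 0.315) and mitochondrial biogenesis (0.293) were called higher without vehicle replicate 1 (adjusted p = 0.000317 and 0.0032), and adipocyte markers (0.148) lower (adjusted p = 0.019). Fatty acid oxidation (0.0515), with 5 of 32 higher, 12 lower and 15 not called, was called lower without vehicle replicate 2, 3 or 4 or 22 h replicate 2, 6 or 7 (adjusted p = 0.0191 to 0.0489). Xenobiotic metabolism (0.0643) was called lower without vehicle replicate 1 or 2 or 22 h replicate 7 (0.0407 to 0.0441). Actin genes (0.0758) were called lower without vehicle replicate 4 (0.0416) and endoplasmic reticulum chaperones (0.0826) higher without 22 h replicate 1, 3 or 7 (0.0201 to 0.0441). All 27 lists not called at 22 h had camera adjusted p from 0.0515 to 0.971, and adjustment over the list alone moved their counts by at most 3 members. The medians, means and test directions differed in sign for acute phase (0.02, -0.17, up), male-biased (0.13, 0.06, down) and vitamin A genes (-0.06, -0.21, up).

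Against vehicle 2023 genes were higher and 2214 lower at 22 h, 4237 or 36.8% of 11508, 325 and 640 of them by at least 2-fold (limma-voom adjusted p < 0.05). Within mice 1 to 12, which include vehicle replicate 1, the number was 782 and within mice 13 to 24 it was 2622. Camera called 10 of 48 lists higher and 11 lower, none with an estimated correlation, and fry called 28. As many or more lists (22 in a fit of these 16 libraries) came up in 7 of 100 splits of the libraries, so the number of lists by itself carried little.

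**Figure D2:**
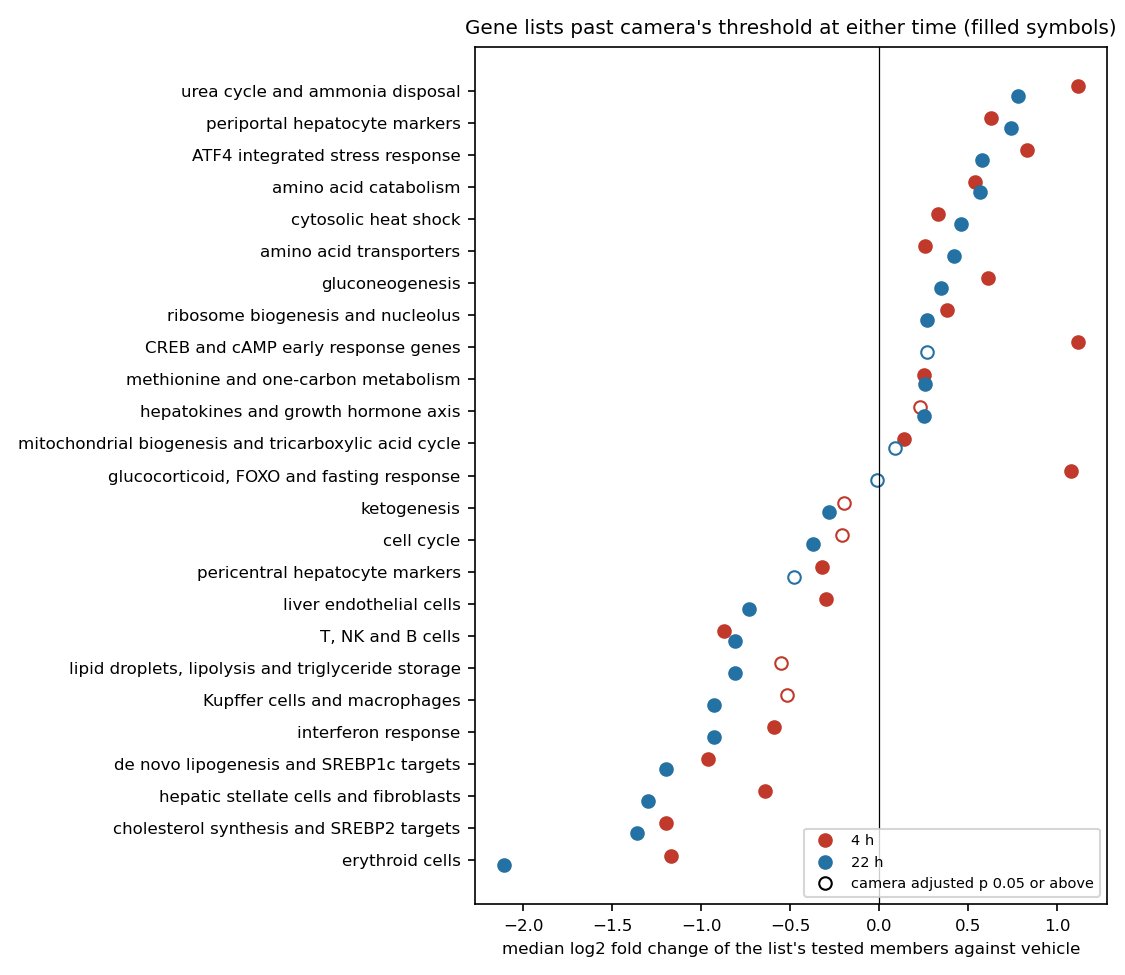
Median log2 fold change against vehicle at 4 h (red) and 22 h (blue) of the lists that passed camera's threshold at either time. Filled points are called lists and open points have an adjusted p of at least 0.05.

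Between 4 h and 22 h after the last injection CREB target genes fell, as did Ppargc1a, G6pc and Pck1 of glucose production. Ppargc1a fell from 137.1 ± 43.51 to 28.24 ± 2.931 CPM and G6pc from 1378 ± 261.6 to 383.3 ± 181.4 CPM (SD, n = 8; log2 fold change -2.24 and -1.99, limma-voom adjusted p = 3.67e-12 and 1.65e-05). Pck1 changed by -0.89 and Per1 by -1.43 (limma-voom adjusted p = 0.00125 and 2.93e-05), all 4 in 8 of 8 livers. The gluconeogenesis list, with 2 of 19 higher, 8 lower and 9 not called, was not called (camera adjusted p = 0.192), and Fbp1 was at 0.11 (limma-voom adjusted p = 0.326). Crem, Nr4a3 and Sik1 changed by -2.20, -4.86 and -2.19 (limma-voom adjusted p = 4.46e-15, 4.42e-13 and 2.28e-12, 8 of 8). Among CREB targets 3 of 23 were higher, 14 lower and 6 not called, also adjusted over the list alone (camera adjusted p = 5.33e-07, and adjusted p = 0.282 with an estimated correlation). Irs2, the phosphatase gene Dusp1, the stress gene Gadd45g and Tat changed by -1.45, -2.53, -3.29 and -1.49 (limma-voom adjusted p = 2.21e-09, 4.4e-09, 3.6e-07 and 9.23e-07, 8 of 8). Glucocorticoid and fasting genes had 1 of 18 higher, 10 lower and 7 not called, against 1, 11 and 6 adjusted over the list alone (camera adjusted p = 0.00315, and adjusted p = 0.98 with an estimated correlation).

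Cholesterol genes and vessel markers kept falling over the same hours. Hsd17b7 of late sterol synthesis changed by -1.04 log2 units (limma-voom adjusted p = 1.03e-06, 8 of 8 livers). The cholesterol list had 8 of 21 lower, none higher and 13 not called, also adjusted over the list alone (camera adjusted p = 0.0304, and adjusted p = 0.98 with an estimated correlation). Leaving out any one of 8 libraries, vehicle replicate 1, 4 h replicates 5 and 7 and 22 h replicates 1, 2, 3, 5 and 7, ended this call (adjusted p = 0.05 to 0.106). Vwf and Oit3, a gene of sinusoidal endothelium, changed by -0.67 and -0.59 (limma-voom adjusted p = 0.00515 and 0.00721, 8 of 8), and Oit3 was not called without 22 h replicates 6 and 7 together (-0.36). Endothelial markers were lower for 7 of 17 and not called for 10, against 11 and 6 adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.98 with an estimated correlation). Here the call was lost without 22 h replicate 6 (adjusted p = 0.0657) or 7 (0.0609).

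The largest rises from 4 h to 22 h were mostly of genes that had fallen at 4 h, and the largest falls were of genes that had risen, all in 8 of 8 livers. Rgs16 rose 137-fold to 139.6 ± 49.06 CPM (SD, n = 8), Depp1 23.8-fold and Arrdc3 18.1-fold (limma-voom adjusted p = 1.05e-09, 9.61e-08 and 1.11e-14). R3hdml, which codes for a secreted protein, rose 25.3-fold, the galactosyltransferase gene B3galt1 6.79-fold and the chemokine gene Cxcl1 5.16-fold (limma-voom adjusted p = 4.06e-09, 2.17e-07 and 7.77e-06). Nr0b2, the repressor SHP of bile acid synthesis, rose 5.08-fold and the stress gene Gadd45a 4.65-fold (limma-voom adjusted p = 1.63e-06 and 6.89e-06). Nr4a3 fell 29.0-fold, the chemokine scavenger gene Ackr3 14.9-fold, Fam222a 13-fold and Gadd45g 9.80-fold (limma-voom adjusted p = 4.42e-13, 0.000564, 4.06e-09 and 3.6e-07). Pde10a, which breaks down cAMP, fell 8.70-fold, the kinase gene Plk3 8.53-fold, the tubulin glycylase gene Ttll8 8.14-fold and Dusp8, a MAP kinase phosphatase, 7.35-fold (limma-voom adjusted p = 7.88e-11, 4.95e-13, 1.95e-08 and 1.76e-08).

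Gcgr and Cyp8b1 were higher at 22 h than at 4 h, by 0.57 and 0.70 log2 units (limma-voom adjusted p = 3.5e-05 and 0.0223, 8 of 8 livers). Cyp8b1 lost its call without 4 h replicate 2 (0.59) or 22 h replicate 7 (0.61). Cyp7a1 (0.53, limma-voom adjusted p = 0.239, 5 of 8) and Srebf1 (-0.23, limma-voom adjusted p = 0.403, 5 of 8) were not called. In the clock list, Dbp and Hlf rose by 1.36 and 0.66 and Cry1 changed by -2.06 (limma-voom adjusted p = 1.53e-09, 3.75e-08 and 4.91e-09, 8 of 8). With 5 of 18 higher, 9 lower and 4 not called, the list as a whole was not called (camera adjusted p = 0.627). Lipogenesis (camera adjusted p = 0.0644) was called lower without vehicle replicate 5, 4 h replicate 4 or 22 h replicate 4 or 6 (adjusted p = 0.0181 to 0.0466). Stellate markers (0.0644) were called lower without 4 h replicate 4 or 22 h replicate 3, 4 or 8 (0.0188 to 0.0438). Erythroid markers (0.122) were called lower without 4 h replicate 4 (0.0482) or 22 h replicate 4 (0.042). The 44 lists not called had camera adjusted p from 0.0644 to 0.965, and in 11 of them, such as urea cycle, amino acid catabolism and methionine genes, the median, mean and test differed in sign. Adjusted over the list alone their counts moved by at most 3 members.

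From 4 h to 22 h 1644 genes rose and 1723 fell, 3367 or 29.3% of 11508, 454 and 272 of them by at least 2-fold (limma-voom adjusted p < 0.05). Upper-quartile scaling gave 2307 and 1171 of 3478, which moved the share of rises from 48.8% to 66.3%. Within mice 1 to 12 there were 2132 such genes and within mice 13 to 24 there were 1859. Camera called 4 of 48 lists, all lower, none with an estimated correlation, and 94 of 100 splits of the 16 libraries gave as many. Fry called 12 lists.

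More genes were changed the same way at both times than independent lists would share, among them Pck1, Tat, Got1, Nnmt, Cth, Ass1 and Gls2 upward and Hmgcs1, Scd1, Thrsp, Orm3 and Ces1g downward. Higher at both times were 1203 genes and lower at both 1299, against 439.7 and 498.3 expected of independent lists, and 177 went opposite ways (limma-voom adjusted p < 0.05). Separate vehicle livers for each comparison left 794 and 732 of the 3142 then changed at 22 h, against 263.6 and 300.6 expected. In simulated unchanged groups no gene was called at either time, so they give no reference for these counts. Changes at the 2 times correlated across genes at r = 0.65, and at 0.533 with separate vehicle livers (0.489 to 0.533 over 20 splits). Genes are not independent replicates. The simulated unchanged groups gave 0.305. They were drawn around the observed vehicle means, which takes out the chance values of these livers, so 0.305 is no reference for r either. Among genes called at 4 h, 44.4% of the change was left at 22 h (41.8% to 44.8% over 20 splits), 46.7% for genes that had risen (45.1% to 46.8%) and 42.5% for genes that had fallen (39.3% to 43.1%). The 4 h change taken on itself across the 2 sets of vehicle livers gave 90.2%. Choosing genes by their 4 h value and chance values of the vehicle livers both lower such a share, and they were not separated. The same 4 h livers stood on both sides of that 90.2%, so the loss from their own chance values is not in it. Vehicle livers were taken only at 22 h. The 4 h change therefore also holds the time since injection, and the share left is not that of the drug alone.

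**Figure D3:**
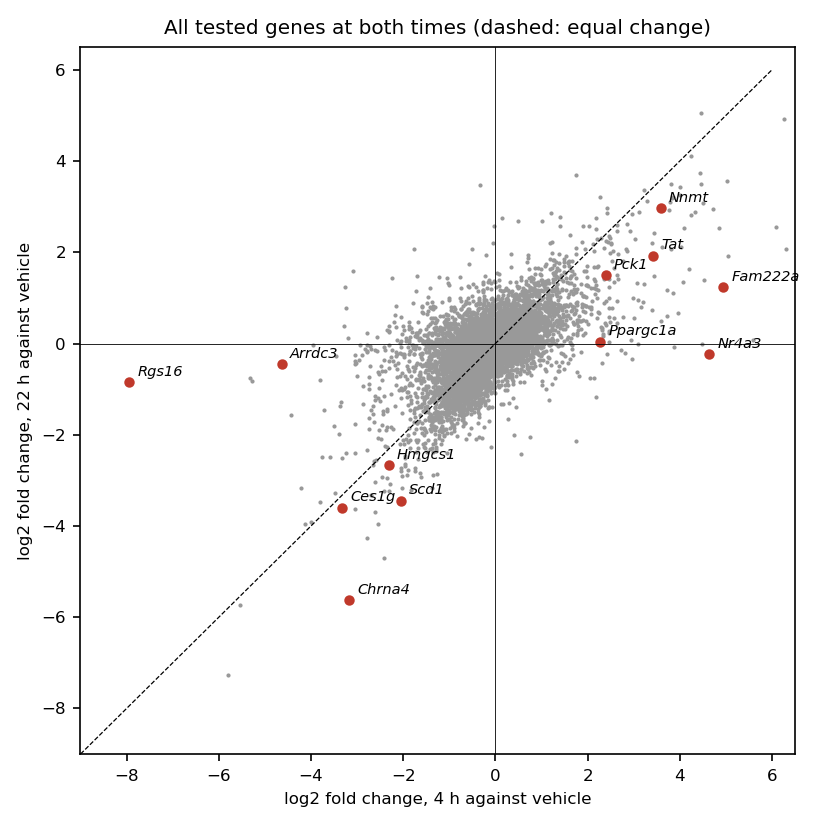
Log2 fold change against vehicle at 4 h (horizontal) and 22 h (vertical) of all tested genes, with a dashed line of equal change and labels on Nnmt, Tat, Pck1, Fam222a, Ppargc1a, Nr4a3, Arrdc3, Rgs16, Hmgcs1, Ces1g, Scd1 and Chrna4.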

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

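Of the tests in this part, the division of libraries in other ways had been fixed earlier, and the tests on the adipose transcripts of vehicle replicate 1 were chosen only after the result was seen.

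Vehicle replicate 1 held more transcripts of fat, muscle and white blood cells than the other vehicle livers. Its adipocyte markers averaged 9.25 log2 CPM, its muscle markers 3.72 and its neutrophil and monocyte markers 3.22. The antibody genes Ighm and Igkc were at 8.29 and 33.6 CPM, the interferon genes Ddx58 and Oasl2 at 95.3 and 59.4, the vessel gene Egfl7 at 22.7, and Ackr3, Nr4a3 and Nfil3 at 46, 5.15 and 23.5, each the highest of the 8. Fh1 was highest too, at 286 CPM. The hepatocyte genes Fbp1 at 743 CPM, Gcgr at 86.3, Slc16a7 at 204 and Rora at 148 were the lowest of the 8, as were the vessel gene Flt4 at 34.5 and Themis at 55.4. This did not hold for hepatocyte genes in general, since its periportal markers averaged 8.506 log2 CPM, against 8.456 in replicate 8. Dixon's test gave 43 outlying values in 366 uses over all libraries, where chance alone gives about 1 in 20, or 18.3, and 19 of the 43 lay in this library.

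The fat transcripts of this library were put to 2 tests. It was the highest of all 24 for 12 of 12 further genes of a brown fat list, such as Cox8b at 90.8 CPM, Ebf2 at 22.1 and Dio2 at 18.0, which may reflect RNA of brown adipose tissue mixed into the library. For Cpt1b the margin was slight, 0.308 against 0.294 CPM. Its Alb was 71.6% of the mean of the other 7 vehicle livers (51900 against 72600 ± 8310 CPM; SD, n = 7), which excluded another tissue under a liver label. A biological cause was not tested.

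Among IUB288 livers, 4 h replicate 4 stood apart in lipid and steroid genes. Its Scd1 at 1790 CPM, Thrsp at 39.8, Pnpla3 at 0.255, Orm3 at 0.219 and Mcm7 at 10.3 were the lowest of 8, as were its adipocyte markers at 5.07 log2 CPM. Cyp17a1 at 575 CPM, Gucy2c at 31.2 and R3hdml at 1.68 were the highest. The remaining outlying values were scattered over other libraries. At 4 h they were Acacb at 235 and Chrna4 at 5.24 CPM in replicate 5 and muscle markers at 1.84 log2 CPM in replicate 3. At 22 h they were Ackr3 at 0.149 CPM in replicate 2, Nfil3 at 9.51 and Ugt1a5 at 5.67 in replicate 4, Crem at 20.9 and Hgd at 866 in replicate 5, Acat2 at 70.6 in replicate 6, Cd79a at 0.0357 in replicate 7 and muscle markers at 2.17 log2 CPM in replicate 8. In vehicle they were Pcx at 528 CPM in replicate 2, Lrp2 at 0.0777 in replicate 3, G6pc at 79.6 in replicate 5 and Nnmt at 22.7 in replicate 8. Dixon's test marks about 1 in 20 groups of 8 by chance, and no library was left out of the results for this reason.

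The genes R3hdml, Cxcl1, Cry1 and Dusp1 each went opposite ways at the 2 times against vehicle. R3hdml changed by -3.08 at 4 h and 1.58 at 22 h (limma-voom adjusted p = 3.35e-06 and 7.19e-06) and Cxcl1 by -1.48 and 0.89 (limma-voom adjusted p = 0.0022 and 0.0112). Cry1, a repressor of the clock, changed by 1.5 and -0.57 (limma-voom adjusted p = 7.75e-08 and 0.0361), and Dusp1 by 1.82 and -0.71 (limma-voom adjusted p = 7.22e-08 and 0.0291). At 22 h Cry1 lost its call without any one of vehicle replicates 2, 4, 7 and 8 and 22 h replicates 1, 2, 3, 4, 5 and 7 (-0.57 to -0.47), and it was at -0.06 within mice 13 to 24 against -1.04 within mice 1 to 12. Dusp1 lost it without vehicle replicate 1 (-0.57), 3 (-0.65) or 8 (-0.66) or 22 h replicate 1 (-0.65) or 5 (-0.61). The 22 h against 4 h comparison is the test of these differences.

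The proliferation genes Foxm1 and Mki67 changed differently from 4 h to 22 h in the 2 runs of mouse numbers. The change in mice 13 to 24 minus that in mice 1 to 12 was -3.03 and -2.62 log2 units (limma-voom adjusted p = 0.0273 each), with 4 livers per group and run. They were the only 2 of 11508 genes past the threshold in the 3 comparisons.

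Other divisions of the same 16 libraries were compared with the real one. The real division changed 5060 genes at 4 h, 3730 at 22 h and 3442 from 4 h to 22 h, each reached by only 1 of 100 splits, the real one, with at most 1487, 1545 and 2 in any other. For lists called by camera at 4 h the real number was 21, reached by 4 of 100 splits, with 22 as the highest other. At 22 h it was 22, reached by 7 of 100 with 24 as the highest, and from 4 h to 22 h it was 4, reached by 94 of 100 with 19 as the highest. The median of the other splits was 0 genes and 11, 14 and 11 lists, so camera called lists where no genes were called. Chance divisions were thus excluded for the gene counts. The list count at 4 h was rarely reached by chance, but chance was not excluded for it or for the other 2 list counts.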

How the results depend on the processing

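Settings chosen only after the data were seen were limma-trend, library quality weights, and the fits without vehicle replicates 2 and 7 and 4 h replicate 8, without 22 h replicates 6 and 7, and, for the shared changes, without vehicle replicate 1. The alternatives that use edgeR or DESeq2 were not run. Except where a difference follows by construction, the cause was not tested.

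No called gene or list changed direction in the settings run for it. Lists were not run within a run of mouse numbers or with limma-trend, and neither lists nor named genes against a fold change of 1.5. With a library left out, 7858 of 7992 gene results stayed called or not called, 93 lost a call and 41 gained one, and of called lists 1055 of 1080 results kept the call and 25 lost it. Under other settings 3556 of 3663 gene results and 510 of 540 list results stayed the same, 46 and 30 lost a call and 61 gene results gained one. Within a run 555 of 666 gene results stayed the same and 101 lost a call. With an estimated correlation camera lost all 45 list calls, leaving 0, 0 and 0.

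Fewer livers and a larger threshold lower counts by construction. With the same number of livers, however, the 2 runs gave 782 and 2622 genes at 22 h, a difference whose cause was not tested. Vehicle replicate 1, with its brown fat transcripts, was 1 of the 4 vehicle livers of mice 1 to 12. From 4 h to 22 h, a comparison without vehicle livers, mice 1 to 12 did not give fewer genes (2132 against 1859). Mice 1 to 12 gave 2144 genes at 4 h (1219 higher, 925 lower), 782 at 22 h (429, 353) and 2132 from 4 h to 22 h (1007, 1125). Mice 13 to 24 gave 2622 at 22 h (1187, 1435) and 1859 from 4 h to 22 h (887, 972). Against a fold change of 1.5 there were 726 (374, 352), 298 (141, 157) and 379 (220, 159). The fry test called 35 lists at 4 h and 12 from 4 h to 22 h, and without a filter camera called 10 in the latter. With a library left out, lists from 4 h to 22 h ranged from 2 to 7, and genes from 4743 to 5253, 3846 to 4281 and 3081 to 3724.

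Residuals of equal replicate numbers correlated at only -0.219 to 0.134. In the 3 comparisons 6, 0 and 4 of the 16 libraries correlated best with the library of their own number, so weak pairing was not excluded. A replicate block gave 5425, 4388 and 3433 genes, 21, 21 and 4 lists and 2756 genes shared. Shared genes were 1526 with split vehicle livers and 1439 at adjusted p 0.01. The share left was 52.1% with all vehicle livers shared, and the correlation 0.69 for genes of at least 1 CPM, 0.533 with split vehicle livers and 0.664 without the 3 libraries. Without vehicle replicate 1 these were 2517, 44.5% and 0.643. Without 22 h replicates 6 and 7 there were 5447, 3421 and 2929 genes, and without the 3 libraries 4692, 4086 and 3252.

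Some list calls were lost under other settings. T, NK and B cells were lost at 4 h with upper-quartile scaling (adjusted p = 0.0519) and with the stricter filter at 4 h (0.144) and 22 h (0.136), and hepatokines at 22 h with that filter (0.0689) and without 22 h replicates 6 and 7 (0.0566). Hepatokines were also lost with quality weights (0.058). Mitochondrial biogenesis at 4 h was lost with the filter (0.0639) and without the 3 libraries (0.0606), and interferon genes and endothelial markers at 4 h with the filter (0.058 and 0.0604). The cell cycle at 22 h was lost by fry (0.153), with quality weights (0.117), the filter (0.0536) and the block (0.0577), and without the 3 libraries (0.115) or 22 h replicates 6 and 7 (0.154). From 4 h to 22 h endothelial markers were lost without 22 h replicates 6 and 7 (0.288) and with quality weights (0.0935), and cholesterol genes by fry (0.0772), with the filter (0.0628) and without the 3 libraries (0.0548).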

Other observations

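The genes of this and the next paragraph were chosen after their values were seen, and in the paragraphs after them the cell type range and the 1 Mb test were chosen only after the result was seen. The clock list was called in none of the 3 comparisons (camera adjusted p = 0.374, 0.778 and 0.627), while single members changed. Arntl, the activator BMAL1 of the clock, rose at 4 h from 2.883 ± 1.057 to 13.57 ± 3.441 CPM (SD, n = 8; log2 fold change 2.31, limma-voom adjusted p = 1.95e-09, 8 of 8 livers) and was not called at 22 h (0.35, limma-voom adjusted p = 0.279, 6 of 8). Nr1d1, the repressor REV-ERB alpha, changed by -0.78 at 4 h and 0.63 at 22 h (limma-voom adjusted p = 0.000545 and 0.00288, 8 of 8). Per2 was not called at 4 h (0.08, limma-voom adjusted p = 0.632, 5 of 8) and changed by -0.52 at 22 h (limma-voom adjusted p = 0.00328, 7 of 8). Ciart (0.10 and 0.11, limma-voom adjusted p = 0.773 and 0.776, 4 and 5 of 8) and Npas2 (0.33 and -0.10, limma-voom adjusted p = 0.646 and 0.91, 7 and 4 of 8) were not called at either time. Vehicle livers of the 4 h time were not analysed here, so the time since injection and the drug cannot be told apart at 4 h. The hour of day of injection or collection is not given in the sources used here.

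Single genes known from the fasted state differed in how they changed. Cpt1a was not called at 4 h or 22 h (0.09 and -0.14, limma-voom adjusted p = 0.365 and 0.137), nor were Pdk4 and Lpin1 at 22 h (-1.24 and -0.37, limma-voom adjusted p = 0.0731 and 0.278). Pdk4 rose by 1.16 at 4 h (limma-voom adjusted p = 0.0429), and by 1.75 without vehicle replicate 1. That call was lost without any one of vehicle replicates 2 to 8 (limma-voom adjusted p = 0.0543 to 0.104), among other libraries. At 22 h Pdk4 was called lower without vehicle replicate 4 or 5 (limma-voom adjusted p = 0.0439 and 0.0344), and Cpt1a without vehicle replicate 1 (limma-voom adjusted p = 0.0334). Igfbp1, a carrier of insulin-like growth factors that insulin represses, changed by 3.62 at 4 h and 2.11 at 22 h (limma-voom adjusted p = 1.15e-08 and 8.85e-05) and the leptin receptor gene Lepr by 1.98 and 1.27 (limma-voom adjusted p = 3.81e-06 and 0.00182). Cps1 and Arg1, the first and last enzymes of the urea cycle, changed by 1.28 and 0.95 at 4 h (limma-voom adjusted p = 1.28e-07 and 1.22e-06), and the pericentral glutamine synthetase gene Glul by -1.02 (limma-voom adjusted p = 3.59e-07). The elongase gene Elovl6 went opposite ways, by 0.68 at 4 h and -0.54 at 22 h (limma-voom adjusted p = 0.000326 and 0.00334), as did the tubulin gene Tubb2a, by 1.00 and -0.83 (limma-voom adjusted p = 0.000258 and 0.00255). Ctsl, a lysosomal protease, changed by 1.05 and 1.25 (limma-voom adjusted p = 5.01e-07 and 1.06e-07). All of those called here with all libraries had 8 of 8 livers on the same side.

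Markers of 5 other cell types of the liver averaged lower at 22 h, by -1.29 ± 0.27 log2 CPM (SE) for stellate cells, -0.85 ± 0.33 for Kupffer cells, -0.74 ± 0.18 for endothelium, -0.73 ± 0.33 for T, NK and B cells and -0.44 ± 0.21 for cholangiocytes. A larger share of hepatocyte RNA would lower all alike. The range over the 5 was 0.859 (exact permutation p = 0.03 over 12870 arrangements). It was 0.639 without vehicle replicate 1 (exact permutation p = 0.131 over 6435) and 0.703 without 22 h replicates 6 and 7 (exact permutation p = 0.215 over 3003). These 5 thus neither excluded nor showed this explanation. The range left out erythroid markers and neutrophil and monocyte markers. Without vehicle replicate 1 the median changes of their members at 22 h were -2.11 and 0.11 log2 units. Foreign tissue in vehicle replicate 1 was excluded, since 52 of 79 members were called lower without it against 53 with it. Without 22 h replicates 6 and 7 the 5 averages were -0.97, -0.60, -0.52, -0.39 and -0.26 in the same order, and an effect of the drug on these cells remains open.

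In vehicle replicates 2 and 7 and 4 h replicate 8, 93 genes were raised and 0 lowered, against at most 20 raised in any other 3 libraries. Of 91 with a position, 71 had another within 1 Mb, against a median of 12 and a highest value of 27 in 10000 random sets. Of 89 searched, 30.3% had a near-identical copy in another gene, against 12.8% of 846 other genes (Fisher exact p = 4.5e-05). Mitochondrial genes such as ATP6 and COX3 are among those with a position and lie within 1 Mb of each other in any case. A reference or a genome that differs over whole regions in these libraries could give this. Reads counted differently between copies could do so for the 27 of 89 genes with a copy, but no such copy was found for the others. For these 27 the 2 explanations cannot be told apart here. Nor can a reference be told from a genome for any of the genes. Mat2a, Prodh, Slc25a1, Per3, Mup3, Gstp1 and H2-K1 are among the genes left uncertain by it, and a biological cause was not tested.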
